A study of Mus musculus with 12 samples.

How the data were processed

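The samples were J1 mouse ES cells and embryoid bodies derived from them, with 3 replicates of each, and every sample had an array of each of the 2 chip types. Each deposited table held an intensity per probe set on a linear scale for the 6 arrays of a chip, made with MAS5 per the submitters' processing notes, with the version not stated. The trimmed mean of each array, leaving out the lowest and highest 2% of values, was close to 1500, as read from the values, so the arrays had been scaled to a common target before deposit. The values were not normalized again for the reported results. Probe sets were named through the platform's annotation table. On chip A 20380 probe sets had 1 gene, 691 had several and 1555 had none listed. On chip B these numbers were 14661, 245 and 7605. The gene identifiers of 20351 and 14486 probe sets matched the mouse reference table, through which 0 symbols were updated. No gene was named from a probe set with several. The 64 control probe sets of each chip were left out.

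Each chip was tested on its own, embryoid bodies against ES cells, on log2(intensity + pseudocount), where the pseudocount was the 20th percentile of all values of the chip (137 on chip A and 253 on chip B). Fold changes are on that scale and understate the changes of low genes. The test was limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) with Benjamini-Hochberg adjustment over the probe sets of the chip and a threshold of 0.05 on the adjusted p. A gene or list is said to have risen or fallen where it passed. The number of arrays, 3 per group and chip, limits the precision. In simulated data on the probe sets of chip A, with 100 probe sets changed by 2-fold and 100 by 4-fold, the procedure recovered 27 and 74 of them, with 1 false call. On chip B it recovered 1 and 37, with 1 false call, and it made 0 calls on either chip where nothing was changed.

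A total of 30 gene lists were fixed before the data were examined, namely pluripotency, formative and primed epiblast, primitive streak and early mesoderm, lateral and cardiac mesoderm, blood and endothelial precursors, extraembryonic endoderm, definitive endoderm, neural ectoderm, surface ectoderm and keratins, trophoblast, Hox genes, feeder fibroblast, macrophage and leukocyte, germ line, 2-cell-like state, LIF and STAT3 response, FGF and ERK feedback, WNT response, BMP and TGF-beta response, epithelial and mesenchymal, DNA methylation and Polycomb, imprinted genes, cyclins and CDK inhibitors, DNA replication and mitosis, hypoxia and glycolysis, NRF2 and oxidative stress, amino acid stress response, p53 targets and apoptosis, cholesterol synthesis and housekeeping. Each was tested with camera in limma, with a preset inter-gene correlation of 0.01, on 1 probe set per gene, wherever at least 5 members were on the chip, with adjustment over the lists of that chip. The same test with a correlation estimated from the residuals stands beside each call, and no list passed with it. The fry test of limma, also planned, asks whether the members change, without comparison to other genes. Among the lists called on chip A its unadjusted p ran from 1.64e-04 for LIF and STAT3 response to 0.185 for hypoxia and glycolysis. It was 0.00211 for pluripotency, 0.00188 for neural ectoderm and 0.0673 for amino acid stress response. Many list genes tested on chip B were also on chip A, and both chips took the same samples, so the list means of both chips are not independent. Member counts use the probe set that stands for each gene, so other probe sets of a member may have passed. They are given with adjustment over all probe sets tested and over the list alone. The intervals given for log2 changes are 95% intervals of the limma fit.

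The genes named in the text were set by a rule fixed before the data were examined. It took 4 pluripotency factors as a check of the labels, the 6 largest rises and 6 largest falls on chip A and 3 of each on chip B, and for each list its called members with the largest changes, up to the number set for that list, with its brightest uncalled member. The largest changes were taken among probe sets with 1 gene that passed the test and whose groups did not overlap. A gene stood for 1 probe set, from chip A before chip B, then by an ID not ending in _x_at, then by the highest mean. The rule was first applied to all probe sets of a chip and then, as worded, to the probe set that stands for each gene, after the first outcome had been seen. A marker fixed in advance is not reported here. No other probe set of a gene named in the text was called in the opposite direction.

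Alternatives fixed in advance were quantile and median scaling, pseudocounts of 1 and of the chip median, a filter on dim probe sets, no intensity trend, the replicate number as a block, the scan day as a random block on chip A, stricter thresholds, another choice of probe set in the lists, and leaving out each array in turn. The fluidics position as a block, counting 1 probe set per gene and scaling on the 100 probe sets present on both chips were chosen after seeing the data. Chip lot differed between the groups on both chips, and every scan day of either chip held 1 group. On chip B each group had a single lot and day, so neither can be told apart from the group. On chip A the ES arrays were scanned on 1 day and the embryoid body arrays on 3, so the day could enter only as a random block, which does not separate it from the group. Within a group, arrays had Spearman correlations across probe sets between 0.917 and 0.952 on chip A and between 0.817 and 0.864 on chip B, and between groups from 0.880 to 0.925 and from 0.639 to 0.758. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.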

Results

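Gene expression was measured in J1 mouse embryonic stem (ES) cells and in embryoid bodies made from them, the cell aggregates in which ES cells begin to differentiate. The ES cells had grown for 2 days on gelatin in medium with 10% serum, leukemia inhibitory factor (LIF), β-mercaptoethanol and sodium pyruvate. The embryoid bodies had been kept for 5 days in bacterial Petri dishes with 10% serum and without those 3 additions. Each culture state had 3 replicate samples, and each sample was hybridized to both arrays of the Affymetrix mouse 430 set, here called chip A and chip B, giving 12 arrays. The median signal of a chip A array lay between 587 and 679, and that of a chip B array between 907 and 996. The number of arrays, 3 per group and chip, limits the precision of every value. Fold changes are on the log2(signal + pseudocount) scale, which understates the changes of low genes. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The labels also put the purity of the ES samples at 95% as judged by eye and name DR4 feeder cells, mouse fibroblasts on which ES cells are grown, as the contaminating type.

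The comparison of both states asked which transcripts changed as ES cells entered differentiation in embryoid bodies. Pou5f1, the transcription factor at the core of the pluripotency network, fell from a signal of 14603 ± 1879.9 in ES cells to 7688 ± 236 in embryoid bodies (SD, n = 3 each), a drop of 1.87-fold with a limma adjusted p of 0.00783. Nanog and Sox2, which act with Pou5f1, did not pass the test. Nanog stood at 5799 ± 598 in ES cells and 5187 ± 451 in embryoid bodies (log2 change -0.16, 95% interval from -0.47 to 0.16). Sox2 stood at 8500.5 ± 1589.7 and 8207 ± 2168 (log2 change -0.07, interval from -0.53 to 0.40). Zfp42, also called Rex1 and a marker of naive pluripotency, fell 3.36-fold, from 9679.5 ± 4722 to 2606 ± 845 (adjusted p = 0.0298). Its signal in ES replicate 3, 4392, lay far below the 11168 and 13478 of ES replicates 1 and 2. The call of Zfp42 was kept without ES replicate 3 and was lost on leaving out any other array, with adjusted p values up to 0.114.

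Across the pluripotency list, of 34 measured members 0 rose, 24 fell and 10 did not pass the test (1 up and 27 down adjusted over the list alone). Fgf4, a growth factor secreted by ES cells, fell by 2.95 ± 0.23 on the log2 scale (SE), or 7.75-fold. Gdf3, a ligand of the TGF-beta family, fell 6.85-fold, and Dnmt3l, a cofactor of de novo DNA methylation, fell 6.16-fold. The limma adjusted p values were 3.95e-04, 2.32e-04 and 0.00212. Lin28a, an RNA-binding protein of early embryonic cells, was the brightest member that did not pass, at 9457 ± 2177 in ES cells and 19798 ± 10756 in embryoid bodies. The mean log2 change of the 32 members on chip A was -1.38, with an adjusted p of 6.10e-16 from the gene list test with its preset correlation and an adjusted p of 0.291 with an estimated correlation. Between arrays from the same fluidics position, the chip A mean was -1.32 for ES replicate 1 and EB replicate 2 and -1.65 for ES replicate 2 and EB replicate 3. The 10 members on chip B moved by a mean of -1.37, with adjusted p values of 6.24e-05 and, with an estimated correlation, 0.214. Only 2 members of the list were on chip B alone, so most of these 10 were also among the 32 on chip A.

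**Figure D1:**
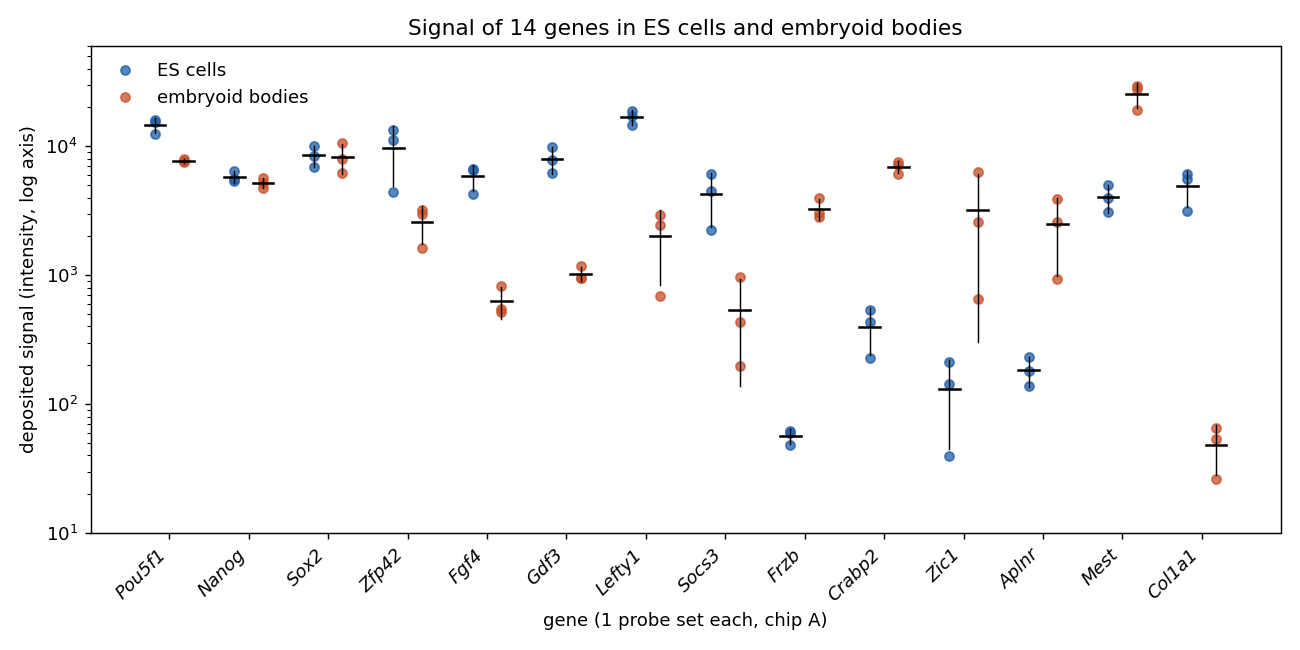
Deposited signal (vertical axis, intensity units, log axis) of 14 genes on chip A, with each ES array in blue and each embryoid body array in orange, a horizontal bar at the mean of 3 arrays and a vertical line of 1 SD to each side. Pou5f1 fell 1.87-fold while Nanog and Sox2 did not pass the test, and Frzb and Crabp2 rose 17.5-fold and 13.6-fold on the log2(signal + pseudocount) scale.

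Genes of the primitive streak and of early neural tissue were among the largest rises in embryoid bodies. Frzb, a secreted WNT antagonist, rose 17.5-fold, from 56.7 ± 7.42 in ES cells to 3289 ± 626 in embryoid bodies (SD, n = 3, adjusted p = 1.41e-04). Aplnr, the apelin receptor of nascent mesoderm, rose 7.16-fold (adjusted p = 0.00734). Rspo3, a WNT agonist measured on chip B, rose 4.88-fold (adjusted p = 0.00612). In the list of primitive streak and early mesoderm genes, of 26 measured members 7 rose, 1 fell and 18 did not pass the test (9 up and 1 down adjusted over the list alone). Foxh1, a partner of Nodal signalling, was the brightest of those that did not pass, with a log2 change of -0.06. The list's mean log2 change on chip A was 0.66 over 25 genes, while its median was 0.17. Its adjusted p was 0.00612, and the adjusted p = 0.394 with an estimated correlation. Within the fluidics positions shared by both groups the means were 0.44 and 0.99.

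Crabp2, which carries retinoic acid inside cells, rose 13.6-fold to 6939 ± 760.0 (adjusted p = 1.53e-04), and Sox11, a transcription factor of neural progenitors, rose 5.00-fold (adjusted p = 0.00332). Zic1, a zinc finger factor of the neural plate, rose from 132 ± 86.9 to 3187 ± 2883 (adjusted p = 0.0198). Its embryoid body signals ran from 652 to 6324, and its adjusted p reached 0.0761 when ES replicate 1, ES replicate 2, EB replicate 2 or EB replicate 3 was left out. In the neural ectoderm list, of 37 measured members 8 rose, 1 fell and 28 did not pass the test (9 up and 2 down adjusted over the list alone). Nes, an intermediate filament of neural stem cells, was the brightest that did not pass, with a log2 change of -0.02 (95% interval from -0.38 to 0.35). Within the fluidics positions shared by both groups the means were 0.41 and 0.58. The list moved by a mean of 0.46 over 37 genes (adjusted p = 0.00904, and adjusted p = 0.291 with an estimated correlation). The call was lost when all probe sets of a gene were averaged (mean 0.39). On chip B its 12 genes had a mean of 0.73 (adjusted p = 0.160).

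In the list of formative and primed epiblast genes, of 18 measured members 4 rose, 4 fell and 10 did not pass the test (7 up and 5 down adjusted over the list alone). Lefty1 and Lefty2, secreted inhibitors of Nodal signalling, both fell. Lefty1 went from 16810.0 ± 2155 to 2024 ± 1189 (SD, n = 3, adjusted p = 0.00366) and Lefty2, on chip B, from 12340.4 ± 3987 to 2269 ± 1228 (adjusted p = 0.00622). Sall2, a zinc finger factor, rose 4.82-fold, from 431 ± 371 to 2239 ± 908 (adjusted p = 0.0381). The call was lost for Sall2 without ES replicate 1 or 2 or EB replicate 1, 2 or 3 (adjusted p up to 0.147). Dnmt3b, a de novo DNA methyltransferase, did not pass, at 15914 ± 5000.4 in ES cells and 18300.0 ± 7202 in embryoid bodies. The list as a whole had a mean log2 change of 0.19 (adjusted p = 0.244).

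Genes that respond to LIF through STAT3 were lower in embryoid bodies, whose medium held no LIF. The cultures differed in more than LIF, and the feeder fibroblast list was also higher in the ES arrays (mean log2 change -0.98). The part of LIF was not tested. Icam1, a cell adhesion receptor, fell 8.18-fold, from 1733 ± 270.1 to 99.4 ± 85.8 (SD, n = 3, adjusted p = 0.00143). Socs3, the feedback inhibitor of this pathway, fell 6.91-fold (adjusted p = 0.00903). Within the LIF and STAT3 list, of 17 measured members 0 rose, 8 fell and 9 did not pass the test (1 up and 11 down adjusted over the list alone). Pim1, a kinase induced by STAT3, did not pass, with a log2 change of -0.99 and an adjusted p of 0.0920. The list's mean log2 change was -1.17 over 17 genes (adjusted p = 2.09e-07, and adjusted p = 0.114 with an estimated correlation). It shared 3 members with other lists, among them Klf4 and Klf5 of the pluripotency list.

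Among WNT response genes, of 22 measured members 4 rose, 1 fell and 17 did not pass the test (5 up and 2 down adjusted over the list alone). Sfrp1, a secreted WNT modulator, rose 3.84-fold to 4259 ± 1732 (adjusted p = 0.0102), and Sp5, a transcription factor induced by WNT, rose 4.25-fold (adjusted p = 0.0423). The receptor gene Fzd7 did not pass, with a log2 change of -0.23. The list's mean of 0.40 had an adjusted p of 0.0437, and an adjusted p of 0.357 with an estimated correlation. Its 9 genes on chip B had a mean of 0.52 (adjusted p = 0.185). The list call was also lost with a mean of 0.44 with fluidics position as a block, 0.46 after median scaling, 0.61 and 0.21 with pseudocounts of 1 and of the chip median, and 0.29 with all probe sets of a gene averaged. It was lost too without ES replicate 1, ES replicate 2, ES replicate 3 or EB replicate 1, with an adjusted p of up to 0.0785. In the BMP and TGF-beta list 3 members rose, 4 fell and 12 did not pass (5 up and 4 down adjusted over the list alone), with Lefty1 and Lefty2 as the largest falls and Skil, a repressor of SMAD signalling, not passing (mean 0.08, adjusted p = 0.252). In the FGF and ERK feedback list 3 rose, 1 fell and 12 did not pass (3 up and 1 down adjusted over the list alone). Etv5, a transcription factor downstream of FGF, fell 2.19-fold (adjusted p = 0.0145, and 0.0572 without ES replicate 1), while Dusp6, an ERK phosphatase, rose 2.73-fold (adjusted p = 0.0397). Calls were lost for Sp5 without ES replicate 1 or 2 or EB replicate 1, 2 or 3 (adjusted p up to 0.139) and Dusp6 without ES replicate 1 or 2 or EB replicate 1, 2 or 3 (adjusted p up to 0.115). The related gene Dusp4 did not pass at a log2 change of 0.45. That list's mean was -0.01 on chip A while its test pointed up (adjusted p = 0.558), and -0.53 over 10 genes on chip B (adjusted p = 0.160).

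**Figure D2:**
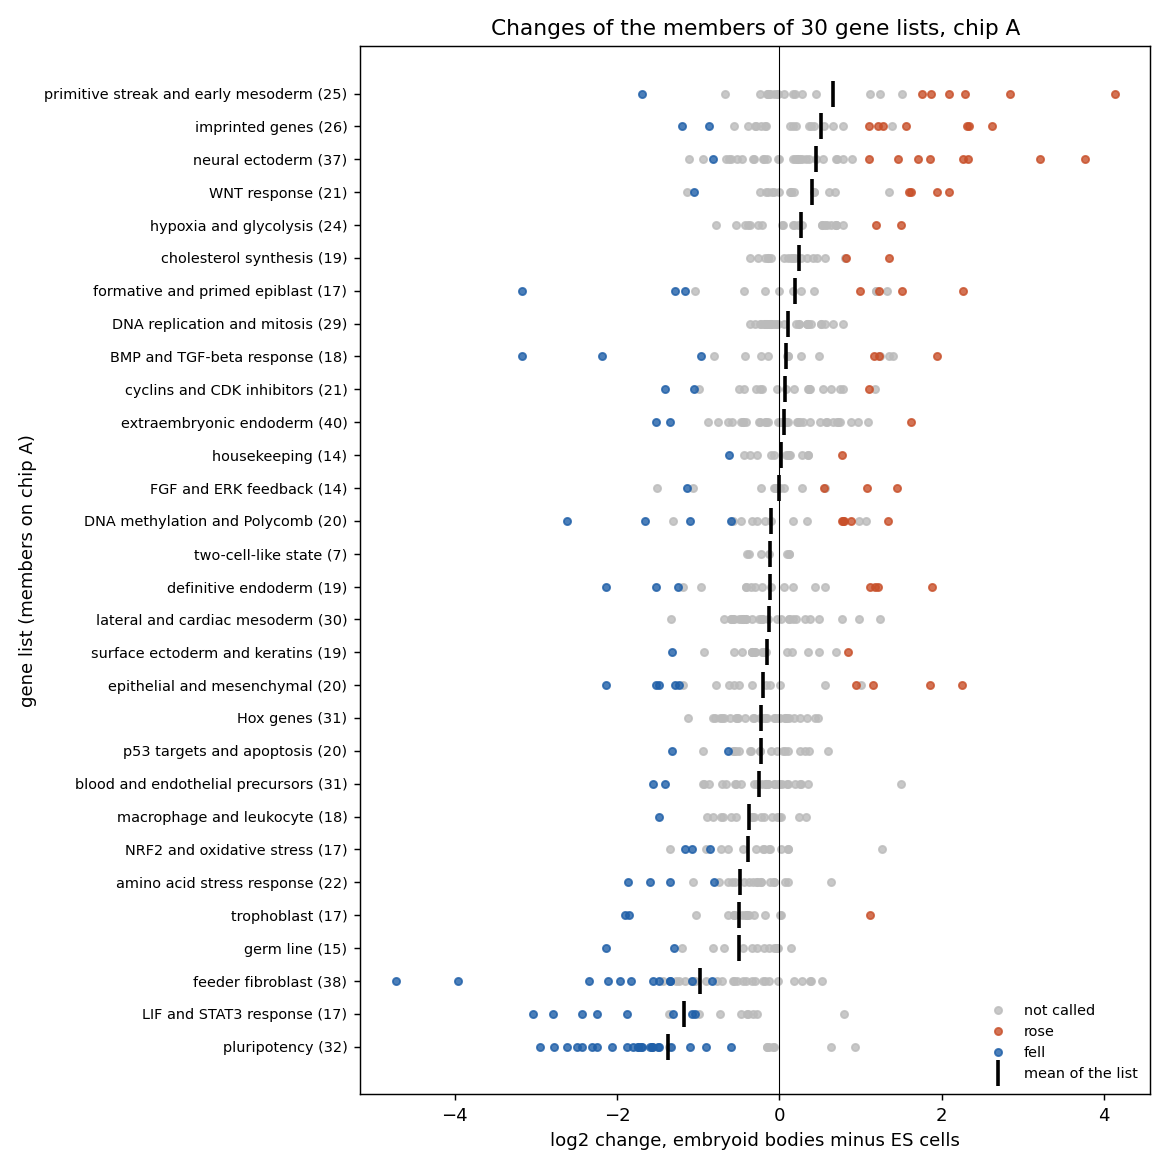
Log2 change from ES cells to embryoid bodies (horizontal axis) of each member of 30 gene lists on chip A (rows, with the number of members measured there), with members that rose in orange, members that fell in blue and members that did not pass in grey. A black tick marks each list's mean, which ran from -1.38 for pluripotency to 0.66 for the primitive streak and early mesoderm.

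Later mesoderm and axial patterning genes gave few or no calls after 5 days. None of the 30 measured lateral and cardiac mesoderm genes and none of the 33 Hox genes passed the limma test. None passed either when adjusted over the list alone, while 5 and 3 of them had an unadjusted p under 0.05. These counts use the probe set that stands for each gene, and other probe sets of a member may have passed. Bmp4, the brightest of the former, had a log2 change of -0.60 (95% interval from -1.34 to 0.15), and Hoxd3, the brightest of the latter, one of 0.72 (from 0.10 to 1.34). Largest sizes among the uncalled members were 1.33 and 1.12 on the log2 scale, so moderate changes were not excluded. Among 31 blood and endothelial genes, 0 rose and 2 fell, namely the surface proteins Pecam1 (2.95-fold lower, adjusted p = 0.0281) and Cd34 (2.65-fold lower, adjusted p = 0.0444), with 0 up and 2 down adjusted over the list alone. The call of Pecam1 was lost without ES replicate 1, ES replicate 2, EB replicate 1 or EB replicate 3 (adjusted p up to 0.119), and that of Cd34 on leaving out any array but EB replicate 2 (up to 0.172). Ramp2, a receptor-modifying protein of vessels, had a log2 change of 0.25 and did not pass. Adjusted p values of the list tests were 0.729, 0.279 and 0.202 in that order.

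Cldn4 and Epcam, proteins of epithelial cell contacts, fell, while endoderm genes went both ways. Cldn4, of tight junctions, fell 4.38-fold, from 4641 ± 677 to 1086 ± 652 (SD, n = 3, adjusted p = 0.0131, and 0.0616 without ES replicate 1), and Epcam, an adhesion molecule, fell 2.87-fold (adjusted p = 0.00964). Cdh11, a mesenchymal cadherin, rose 4.75-fold (adjusted p = 0.0128, and 0.0546 without EB replicate 3). In the epithelial and mesenchymal list, of 20 measured members 4 rose, 5 fell and 11 did not pass the test (5 up and 7 down adjusted over the list alone), and Vim, the mesenchymal intermediate filament, did not pass at a log2 change of 0.01. In the definitive endoderm list, of 20 measured members 4 rose, 3 fell and 13 did not pass the test (4 up and 5 down adjusted over the list alone). Cxcr4, a chemokine receptor, rose 3.68-fold (adjusted p = 0.0186, up to 0.0687 without ES replicate 1 or any of the EB replicates), and Trh, a neuropeptide precursor, did not pass (log2 change -0.97, adjusted p = 0.0564). In the extraembryonic endoderm list, of 40 measured members 1 rose, 2 fell and 37 did not pass the test (2 up and 2 down adjusted over the list alone). Dkk1, a secreted WNT antagonist, rose 3.08-fold (adjusted p = 0.0112). Lamc1, a laminin chain, and Nid1, which binds laminin, fell 2.55-fold and 2.86-fold (adjusted p = 0.00153 and 0.0396), and Apoe, an apolipoprotein, did not pass at -0.59. In the surface ectoderm list 1 rose, 1 fell and 18 did not pass (1 up and 2 down adjusted over the list alone), namely the keratin Krt18 (1.79-fold higher) and the desmosome protein Perp (2.50-fold lower), with Krt8, a simple epithelial keratin, at a log2 change of 0.36. Calls were lost for Dkk1 without EB replicate 1 or 3 (adjusted p up to 0.0524), Nid1 without ES replicate 1, 2 or 3 or EB replicate 1 or 3 (adjusted p up to 0.139), Krt18 without ES replicate 1 or 2 or EB replicate 1, 2 or 3 (adjusted p up to 0.0844) and Perp without ES replicate 1 or 3 or EB replicate 1 or 3 (adjusted p up to 0.0975). The feeder fibroblast list was higher in the same ES arrays, with a mean log2 change of -0.98. None of these 4 lists passed as a whole (adjusted p = 0.279, 0.750, 0.480 and 0.719).

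Several of the largest falls on chip A were in genes that fibroblasts express strongly. Col1a1, the main collagen of fibroblasts, went from 4923 ± 1554 in ES cells to 48.6 ± 20.2 in embryoid bodies (SD, n = 3, adjusted p = 1.41e-04). S100a4, a calcium-binding protein of fibroblasts, fell 15.5-fold and Fbln2, a matrix protein, fell 5.07-fold (adjusted p = 2.32e-04 and 0.00172). Bgn, a matrix proteoglycan, Mgp, an inhibitor of mineralization, and Tm4sf1, a surface protein, are not in the feeder fibroblast list. They fell with log2 changes of -3.72, -3.70 and -3.17 (adjusted p = 3.63e-05, 0.00275 and 0.00678). In the feeder fibroblast list, of 38 measured members 0 rose, 12 fell and 26 did not pass the test (0 up and 20 down adjusted over the list alone). Acta2, a smooth muscle actin, was the brightest that did not pass, at 8158 ± 3117 and 7123 ± 4077. The list's mean log2 change was -0.98 (adjusted p = 2.92e-08, and adjusted p = 0.394 with an estimated correlation). The labels give DR4 feeder cells as the contaminating type of the ES samples, with a purity of 95%, and give no purity for the embryoid bodies. Feeder content can therefore not be compared between the groups from the labels. Between arrays from the same fluidics position, the mean was -0.97 for ES replicate 1 and EB replicate 2 and -0.40 for ES replicate 2 and EB replicate 3. On chip B the 10 members had a mean of -0.29 (adjusted p = 0.368).

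**Figure D3:**
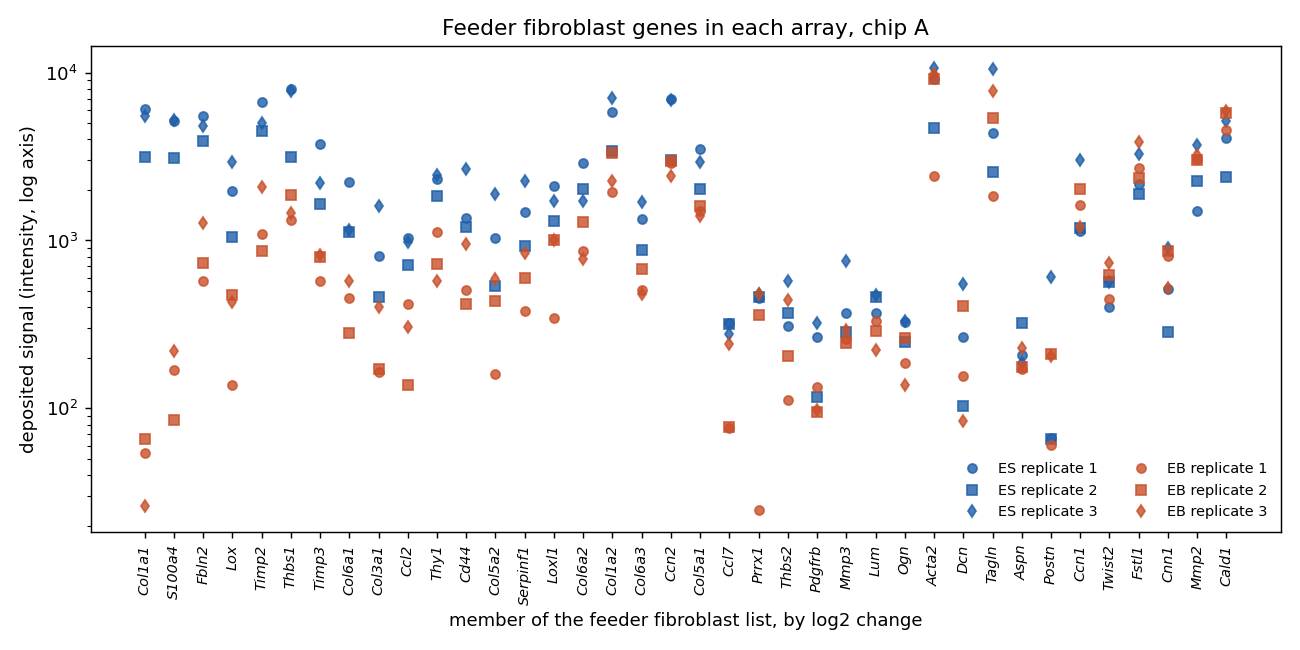
Deposited signal (vertical axis, intensity units, log axis) of the 38 feeder fibroblast genes on chip A (horizontal axis, ordered by log2 change), with ES arrays in blue, embryoid body arrays in orange and a symbol for each replicate. Col1a1 stood near 4923 in ES cells and 48.6 in embryoid bodies, while Acta2 had similar means in both groups.

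The trophoblast and germ line lists, fixed as markers of other cell types, were lower in embryoid bodies with the preset correlation. Whether the dishes held such cells was not tested. Rhox5 and Rhox9, X-linked homeobox genes, fell 3.73-fold and 3.60-fold (limma adjusted p = 9.52e-04 and 0.00801, n = 3). In the trophoblast list, of 17 measured members 1 rose, 2 fell and 14 did not pass the test (1 up and 2 down adjusted over the list alone), and Bex1 stayed at 0.02 on the log2 scale without passing. The list mean was -0.50 (adjusted p = 0.0142, and adjusted p = 0.291 with an estimated correlation), and its adjusted p was 0.0602 without ES replicate 3. The call was also lost with fluidics position as a block, at a mean of -0.44. Ifitm3 and Ifitm1, interferon-inducible membrane proteins of early germ cells, fell 4.39-fold and 2.45-fold (adjusted p = 3.95e-04 and 0.00841). They were the 2 members called in the germ line list, where 15 did not pass (0 up and 4 down adjusted over the list alone), Kit, a growth factor receptor, among them at 0.14. The germ line mean was -0.50 (adjusted p = 0.0142, and adjusted p = 0.394 with an estimated correlation).

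Several imprinted genes, expressed from a single parental allele, rose in embryoid bodies. Mest rose 6.14-fold, from 4025 ± 978 to 25362 ± 5528 (SD, n = 3), and Ndn, a growth regulator of postmitotic neurons, rose 5.06-fold (both with a limma adjusted p of 5.19e-04). In the imprinted list, of 28 measured members 7 rose, 2 fell and 19 did not pass the test (9 up and 2 down adjusted over the list alone). Meg3, a maternally expressed RNA, did not pass at 0.21. The list mean was 0.51 over 26 genes on chip A (adjusted p = 0.00244, and adjusted p = 0.394 with an estimated correlation), and 0.20 with a median of -0.02 over 11 genes on chip B (adjusted p = 0.865).

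Chromatin and cell cycle regulators changed individually and not as lists. Jarid2, a subunit that targets Polycomb repressive complexes, fell 3.14-fold, from 18348 ± 3251 to 5720.3 ± 821 (SD, n = 3, adjusted p = 0.00143). In the DNA methylation and Polycomb list, of 22 measured members 5 rose, 4 fell and 13 did not pass the test (7 up and 7 down adjusted over the list alone). Ccne1, which drives entry into S phase, fell 2.65-fold (adjusted p = 0.00528), and Cdk4, the partner of D-type cyclins, rose 2.15-fold (adjusted p = 0.00425). In the list of cyclins and CDK inhibitors, of 21 measured members 1 rose, 2 fell and 18 did not pass the test (3 up and 2 down adjusted over the list alone), with the mitotic kinase Cdk1 not passing at 0.08. By the probe set that stands for each gene, none of the 29 replication and mitosis genes passed the limma test (7 had an unadjusted p under 0.05). Pcna, the replication clamp, was the brightest of them, with a log2 change of 0.51 (95% interval from 0.16 to 0.86). Other probe sets of members did pass. For Bub1b, of the replication list, 1 fell and another rose on chip B, with log2 changes of -1.44 and 1.89. For Cbx7, of the methylation and Polycomb list and not called in its count, 1 fell on chip A and 1 on chip B, each with a log2 change of -2.36. The chip A means of these 3 lists were -0.10, 0.07 and 0.11 (adjusted p = 0.729, 0.357 and 0.167), and on chip B -0.80 over 6 genes, -0.76 over 6 and -0.14 over 10 (adjusted p = 0.160, 0.167 and 0.518). The chip A median of the replication list was -0.01, and the test statistic of the methylation and Polycomb list on chip A pointed up while its mean was negative.

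Over all of chip A, 1425 of 22626 probe sets passed the limma test with Benjamini-Hochberg adjustment. Of these 767 rose and 658 fell, 892 of them by at least 2-fold. Counting 1 probe set per gene, 424 genes rose and 426 fell among 12393. The largest rises were in Gas1, a growth arrest protein of the cell surface (22.0-fold, adjusted p = 6.61e-04), Frzb, Crabp2, Ptn, a heparin-binding growth factor (7.68-fold, adjusted p = 0.00122), Aplnr and Zic1, whose call was lost without ES replicate 1 or 2 or EB replicate 2 or 3 (adjusted p up to 0.0761). The largest falls were in Col1a1, S100a4, Bgn, Mgp, Lefty1 and Tm4sf1. The share of calls that were rises depended on the scaling of the arrays, at 53.8% as deposited, 63.5% after median scaling and 36.8% after scaling on the 100 probe sets that both chips share, a setting chosen after seeing the data. The count of calls was 466, 874, 434, 625 and 644 without ES replicate 1, ES replicate 2, EB replicate 1, EB replicate 2 and EB replicate 3 in that order, and 2092 without ES replicate 3. The lot of the chips differed between the groups on both chip types, so lot and group cannot be told apart. Each scan day of chip A also held 1 group, with the ES arrays on 1 day and the embryoid body arrays on 3. The ratio of the 3' to the 5' actin probe sets, a sign of RNA quality, was 1.11 ± 0.0277 in ES arrays and 1.36 ± 0.274 in embryoid body arrays (SD, n = 3). ES replicate 3 stood apart from its group, with a mean Spearman correlation to the embryoid body arrays of 0.921, against 0.897 and 0.886 for ES replicates 1 and 2.

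Chip B, which carries less well characterized transcripts, gave large changes in both directions. Over all its probe sets the largest called log2 changes were 4.42 and -4.38. Among genes with no probe set on chip A, the largest rises were in the transcript BC048507, in Lgi3, a secreted leucine-rich protein, and Flrt3, a leucine-rich adhesion protein, at 12.3-fold, 12.2-fold and 11.8-fold. Flrt3 went from 243 ± 58.6 in ES cells to 5761 ± 1924 in embryoid bodies (SD, n = 3, adjusted p = 0.00104). The largest falls among genes with no probe set on chip A were in Rbmxl2, an RNA-binding protein, Cobl, an actin nucleator, and the transcript 2900026A02Rik, at 17.8-fold, 7.96-fold and 7.10-fold. Rbmxl2 went from 10853 ± 3064 to 406 ± 310.3 (adjusted p = 0.00104). Of the 17 lists with enough members on chip B, only pluripotency passed. The largest mean among the others was 1.12 for 5 definitive endoderm genes (adjusted p = 0.180), and the means of lateral and cardiac mesoderm, Hox, extraembryonic endoderm, BMP and TGF-beta, and epithelial and mesenchymal genes were 0.18, 0.37, 0.33, -0.21 and -0.24 (adjusted p = 0.475, 0.342, 0.475, 0.865 and 0.434). The medians of the extraembryonic endoderm and the BMP and TGF-beta lists had the opposite sign, at -0.06 and 0.10. In all, 2407 of 22511 probe sets passed, of which 1301 rose and 1106 fell, 2084 by at least 2-fold, and by 1 probe set per gene 594 genes rose and 621 fell among 9607. Of 58 genes called on both chips, each by the probe set that stands for it on that chip, 52 had the same direction, whereas 302 of the 484 genes called on chip B and measured on chip A did. Among genes with at least 2 called probe sets on the same chip, 41 of 118 were called in both directions on chip B and 0 of 164 on chip A. The share of rises was 54.1% as deposited and 77.5% after scaling on the shared probe sets (2212 rose and 641 fell), which moved the median log2 change of all probe sets from -0.00 to 0.19. The count of calls was 1029, 1411, 1546, 934 and 1165 without ES replicates 1, 2 and 3 and EB replicates 1 and 3 in that order. Chip lot and scan day each differed between the groups on chip B, so neither can be told apart from the group.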

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

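Fluidics position as a block, 1 probe set per gene, and scaling on the probe sets shared by both chips were chosen after seeing the data, as were the checks of single genes without an intensity trend, with scan day as a random block and among brighter probe sets. Over 97 named genes and 47 list shifts, 0 called values changed direction, and 1366 of 1531 gene values and 649 of 688 list values kept their side of the threshold. Of the gene values 142 no longer passed and 23 newly passed, and of the list values 33 and 6. Against 1425 (767 rose, 658 fell) on chip A and 2407 (1301 rose, 1106 fell) on chip B, chip A gave 844 (425 rose, 419 fell) without the intensity trend, 342 (158 rose, 184 fell) at an adjusted p under 0.01, 892 (444 rose, 448 fell) with at least a 2-fold change and 2243 (1221 rose, 1022 fell) with scan day as a random block, whose estimated correlation was -0.11. With only 1 probe set per gene tested, 507 rose on chip A, and chip B gave 1457 (725 rose, 732 fell). At an adjusted p under 0.01 chip B gave 564 (319 rose, 245 fell), and scaled on the shared probe sets 2853 (2212 rose, 641 fell). The stricter thresholds and 1 probe set per gene lower counts by construction. The negative scan day correlation lowers the modelled variance of the mean of the ES arrays, which shared a day. That can add calls by construction. For the other settings the cause was not tested. With 1 array left out, chip A counts ran from 434 to 2092 called, 206 to 1161 rose and 228 to 931 fell, and chip B counts from 934 to 1806, 502 to 949 and 430 to 857. Of 66 named genes called, 41 stayed called in every such fit and 25 did not, and of 13 lists called 9 stayed and 4 did not. In those fits the WNT response mean ran from 0.34 to 0.44, hypoxia from 0.16 to 0.38, trophoblast from -0.53 to -0.45, amino acid stress from -0.63 to -0.35, cholesterol synthesis from 0.16 to 0.31, macrophage and leukocyte from -0.42 to -0.31 and, on chip B, DNA methylation and Polycomb from -1.01 to -0.62, the last 3 passing in some fits and not with all arrays. With an estimated correlation the list calls were lost with the means unmoved, on chip A pluripotency -1.38, primitive streak and early mesoderm 0.66, neural ectoderm 0.46, trophoblast -0.50, feeder fibroblast -0.98, germ line -0.50, LIF and STAT3 response -1.17, WNT response 0.40, imprinted genes 0.51, hypoxia and glycolysis 0.27, NRF2 and oxidative stress -0.39 and amino acid stress response -0.49, and on chip B pluripotency -1.37. The estimated correlation on chip A was -6.27e-04 for LIF and STAT3 response, 9.03e-04 for neural ectoderm, -0.0429 for WNT response and -0.0364 for trophoblast. These values lie under the preset 0.01, so a higher correlation did not cost those lists their calls. In the other called lists it was above the preset, up to 0.292 for feeder fibroblast. The WNT response no longer passed at 0.46 with median scaling, 0.61 with a pseudocount of 1, 0.21 with the chip median as pseudocount and 0.29 as a mean over all probe sets of a gene, where neural ectoderm did not pass either (0.39). Hypoxia no longer passed after quantile normalization (0.24), and cholesterol synthesis newly passed after median scaling (0.32). With fluidics position as a block the mean was -0.44 for trophoblast, 0.44 for the WNT response, 0.15 for hypoxia, -0.32 for NRF2 and -0.23 for amino acid stress, all without passing, while cholesterol synthesis passed at 0.28. Beyond that, the cause of the changed list calls was not tested. Arrays with the same replicate number did not deviate together (correlations of their deviations -0.07, 0.04 and -0.01 on chip A, -0.02, -0.03 and -0.02 on chip B), and with the replicate block 1136 probe sets were called on chip A and 2107 on chip B, with no list call changed and 5 named genes that no longer passed and 1 that newly passed. In simulated data 27 of 100 changes of 2-fold were recovered on chip A and 1 of 100 on chip B. Only 200 probe sets were changed there, against 1425 and 2407 called in the real data. The adjustment was therefore stricter in the simulation, and these shares do not give the recovery in the real data.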

Other observations

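The mean log2 changes of the lists of metabolism and stress genes on chip A lay between -0.49 and 0.27. Slc7a3, a cationic amino acid transporter, fell 3.02-fold, from 18750.5 ± 4338 in ES cells to 6198 ± 1765 in embryoid bodies (SD, n = 3, limma adjusted p = 0.00725), and Slc7a5, a transporter of large neutral amino acids, fell 3.63-fold (adjusted p = 0.0145). In the amino acid stress list, of 22 measured members 0 rose, 4 fell and 18 did not pass the test (0 up and 4 down adjusted over the list alone), and Asns, which makes asparagine, did not pass at -0.37 on the log2 scale. Its mean was -0.49 (adjusted p = 0.00723, and adjusted p = 0.442 with an estimated correlation), with an adjusted p of up to 0.123 without ES replicate 3 or EB replicate 1. With fluidics position as a block the mean was -0.23 and did not pass. Gclm, a subunit of the enzyme that starts glutathione synthesis, fell 2.10-fold (adjusted p = 0.0102), and Gpx3, a glutathione peroxidase, fell 2.24-fold (adjusted p = 0.0219). In the NRF2 and oxidative stress list, of 17 measured members 0 rose, 3 fell and 14 did not pass the test (1 up and 6 down adjusted over the list alone), with Txn1, a thioredoxin, at 0.11 and a list mean of -0.39 (adjusted p = 0.0142, and adjusted p = 0.357 with an estimated correlation). That call was lost with fluidics position as a block, at a mean of -0.32. In the hypoxia and glycolysis list, of 26 measured members 2 rose, 0 fell and 24 did not pass the test (6 up and 0 down adjusted over the list alone), with Ddit4 and Egln1 higher by 2.83-fold and 2.28-fold. Ldha, lactate dehydrogenase, stood at 0.70 without passing and the list had a mean of 0.27 (adjusted p = 0.0142, and adjusted p = 0.482 with an estimated correlation). On chip B the mean of its 7 genes was -0.29 (adjusted p = 0.368). The hypoxia call was lost without ES replicate 1 or EB replicate 1 (adjusted p up to 0.124), after quantile normalization (mean 0.24) and with fluidics position as a block (mean 0.15). In the cholesterol synthesis list, of 20 measured members 2 rose, 0 fell and 18 did not pass the test (2 up and 0 down adjusted over the list alone), namely Hmgcs1 (2.55-fold) and Stard4 (1.76-fold), and Fdps, of the mevalonate pathway, did not pass at 0.27 (mean 0.24, adjusted p = 0.0714, and 0.13 on chip B, adjusted p = 0.561). In the list of p53 targets, of 20 measured members 0 rose, 2 fell and 18 did not pass the test (0 up and 2 down adjusted over the list alone), with Mcl1 1.55-fold and Perp 2.50-fold lower, and Ccng1 did not pass at -0.37 (mean -0.23, adjusted p = 0.244). Calls were lost for Slc7a5 without ES replicate 1 or EB replicate 2 (adjusted p up to 0.0589), Gpx3 without ES replicate 1 or EB replicate 1, 2 or 3 (adjusted p up to 0.0878), Ddit4 without ES replicate 2 or EB replicate 1, 2 or 3 (adjusted p up to 0.0958), Egln1 without ES replicate 1 or 3 or EB replicate 1 or 3 (adjusted p up to 0.144), Hmgcs1 without ES replicate 2 or EB replicate 1, 2 or 3 (adjusted p up to 0.0959), Stard4 without ES replicate 1 or 3 or EB replicate 1, 2 or 3 (adjusted p up to 0.146), Mcl1 without ES replicate 1 or EB replicate 1, 2 or 3 (adjusted p up to 0.0869) and Perp without ES replicate 1 or 3 or EB replicate 1 or 3 (adjusted p up to 0.0975).

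Of the macrophage and leukocyte genes, 0 rose, 1 fell and 17 did not pass (0 up and 1 down adjusted over the list alone), with Laptm5, a lysosomal protein of blood cells, 2.79-fold lower, and Csf1r, the receptor that defines this lineage, stood at 1339.8 ± 559 in ES cells and 864 ± 300.0 in embryoid bodies. The list mean was -0.37 (adjusted p = 0.104). Among genes of the 2-cell-like state, 0 rose and 0 fell in the limma test among 8 measured, with 0 at an unadjusted p under 0.05 and Eif1a at -0.22 (mean -0.11, adjusted p = 0.719). These counts use the probe set that stands for each gene. Another, dim probe set of a member rose from 11.8 to 121 (log2 change 0.78, limma adjusted p = 0.0381). In the housekeeping list 1 rose and 1 fell among 14 (1 up and 1 down adjusted over the list alone), namely Ywhaz (1.71-fold higher) and Hprt (1.54-fold lower), while Eef1a1, a translation factor, did not pass at 0.09 (mean 0.02, adjusted p = 0.719). Calls were lost for Laptm5 without ES replicate 1 or 2 or EB replicate 1, 2 or 3 (adjusted p up to 0.0939), Ywhaz without ES replicate 1 or 2 or EB replicate 1, 2 or 3 (adjusted p up to 0.0870) and Hprt without ES replicate 1 or 2 or EB replicate 1, 2 or 3 (adjusted p up to 0.184).

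The tests of feeder content, of embryoid body RNA in ES replicate 3 and of the parental origin of imprinted genes were chosen only after the results they concern had been seen, as was the correlation over shared probe sets. Feeder cells carried into the ES samples are a candidate source of the higher fibroblast transcripts there. Their share could differ between the samples, though nothing in the labels says that these came from separate dishes. The 12 members that fell had a median log2 difference of -0.55 in ES replicate 2 from ES replicates 1 and 3, outside the -0.25 to 0.25 of the middle 95% of 10000 random lists of that size and level, and the 26 uncalled members one of -0.68. Matrix gene expression by the ES cells themselves that varied between samples would give the same values and stays open, as does a change with differentiation. Of the 38 members 18 had an embryoid body mean at or above the chip median and 1 was held by another list, and the most abundant in ES cells, named after their values were seen, were Acta2 (8158 there and 7123 in embryoid bodies), Thbs1 (6293 and 1548) and Tagln (5818 and 4983).

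ES replicate 3 lay nearer the embryoid bodies on chip A than ES replicates 1 and 2, with a mean Spearman correlation to them of 0.921 against 0.897 and 0.886. Embryoid body RNA in that sample would imply the same share from every gene, and the share was 29.1% (95% bootstrap interval 26.4 to 31.2) over all 689 genes that rose without that array, 31.2% (21.6 to 42.1) over the 61 that rose from below the pseudocount and 49.6% (43.6 to 54.7) over 637 genes that fell, with no overlap between rises and falls. The bootstrap resampled genes, which are not independent, within 1 array, so the intervals leave out the spread between samples. The genes were chosen by their difference from ES replicates 1 and 2, so noise in those arrays can raise each share. Of 16 chip A genes at least 10 times higher in embryoid bodies than in ES replicates 1 and 2, chosen without ES replicate 3, 3 (Gas1, Frzb and Crabp2) stood there under the 21.6% share's level from the lowest embryoid body array by more than a factor of 2 (36 of 65 on chip B), Frzb at 62.2 against 609, which argues against such RNA as the whole cause. An effect of that single array was not settled by 3807 genes with a probe set on each chip, which are not independent replicates. The deviations of ES replicate 3 on both chips correlated there with a Pearson r of 0.0708 (95% interval 0.0370 to 0.103). On chip B the log2 changes of 2 probe sets of a gene had an r of 0.0969, so this comparison could miss a recurring deviation. Over the 100 probe sets present on both chips r was 0.635, so for these the deviation recurred on the second array. ES replicate 2 gave 0.0712 and 0.584. On chip B too, ES replicate 3 was nearest the embryoid bodies, at a mean Spearman correlation of 0.710 against 0.687 and 0.686. Partial differentiation of that sample was not tested and stays open. Its poly-A control signals were 2.44 times the mean of ES replicates 1 and 2 on chip A and 2.54 times on chip B. Its hybridization control signals were 0.405 times the mean of those replicates on chip A and 0.429 times on chip B.

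Chip B gave 2407 calls against 1425 on chip A. Once both were scaled on their shared probe sets, chip B gave 2853 calls and chip A 1450. That scaling moved the median log2 change of chip B to 0.19 and could itself add calls. It therefore cannot decide whether the scaling of the arrays was a cause. Chip B also gave more calls than chip A after quantile normalization (2247 and 1336) and after median scaling (2411 and 1406). Of the 100 shared probe sets 21 were called on chip B and 11 on chip A (2 on both, exact test two-sided p = 0.0872), so a lot or scan day effect of chip B cannot be told apart from the group. Probe sets that do not follow their named gene stay open too. Of 484 genes called on chip B, 62.4% had the same direction on chip A (exact 95% interval 57.9 to 66.7), between the bounds set for either answer. Among genes called on neither chip the share was 52.7%. The log2 changes of 2 probe sets of a gene had a Pearson r of 0.0969 on chip B and 0.515 on chip A. Called probe sets of a gene went both ways for 41 of 118 genes on chip B and 0 of 164 on chip A. Such disagreement was thus present on chip B, while its part in the extra calls was not tested. The shared probe sets had the same direction in 50 of 100, though their changes correlated at 0.626, with means of 0.13 on chip A and -0.28 on chip B. No biological explanation was tested for a difference between chips.

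A hypothesis was that paternally expressed imprinted genes had larger log2 changes than maternally expressed ones. The 17 paternally expressed members had a mean log2 change of 0.73 ± 0.989 (SD), with 5 that rose and 1 that fell, and the 7 maternally expressed members one of -0.21 ± 0.615, with 0 and 1. The exact permutation test over 346104 assignments gave a one-sided p of 0.0106 and a two-sided p of 0.0298. Not all 28 measured members of the list, of which 7 rose and 2 fell, entered the test. The members left out could change its result. Genes of the same imprinted cluster are not independent, and the test was chosen on the data it ran on, so the difference may not hold in other samples.

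The 6 arrays of a chip can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, 1 of these 10, called 1425 probe sets on chip A and 2407 on chip B, and the highest of the other splits called 0 on chip A and 0 on chip B in limma. Every other split puts ES and embryoid body arrays on the same side, so the difference between the groups adds to the spread within a side. Few calls follow from that by construction, and the 0 does not measure false calls.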
